A study of Priestia megaterium
Ketogulonicigenium vulgare WSH-001 and Ketogulonicigenium vulgare WSH-001 with 6 samples.

How the data were processed

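Transcription of Ketogulonicigenium vulgare was measured on 6 Agilent 2-colour expression arrays, 3 of co-cultures with Bacillus megaterium and 3 of mono-cultures. Per the labels, each culture's RNA was labelled with Cy5 and hybridised against a common reference labelled with Cy3, a pool of all 6 cultures, and no dyes were swapped. The groups and replicate numbers were taken from the sample titles. The labels call the samples biological replicates and give no further detail on how the cultures were kept apart, so the p-values measure the spread between these samples.

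The scanner output was made with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, each spot has an intensity in each channel as the median brightness of its pixels, a median local background intensity, and a processed intensity that the software had background-subtracted, detrended over the array and dye-normalised. The deposited log10 ratio of each spot is the Cy5 over the Cy3 processed intensity, and it was checked against those columns and then not used further. The authors' deposited value table holds log2 ratios of Cy5 over Cy3. Its unit was worked out here by setting each column against the processed signals of the same array: across IDs, r was between 0.988 and 0.999 with slopes of 0.964 to 0.998, while r with any other array was at most 0.838. No centring of single IDs was seen, the direction is that of Cy5 over Cy3, and the rule by which the table's IDs were chosen is not given in the sources used here. The column medians were -0.05, -0.03 and -0.04 for co-culture replicates 1, 2 and 3, and 0.27, 0.30 and 0.32 for the mono-culture ones. IDs of the KVU_PA and KVU_PB series are spelled slightly differently there and were renamed to match, 9.16% of the IDs listed. The design of the probes, the genome build and the annotation behind the IDs are not given in the sources used here.

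Each array has 15744 spots in 192 rows and 82 columns: 15208 spots of 3060 IDs and 536 control spots, of which 77 are negative controls. An ID has 5 spots (2968 IDs) or 4 spots (92 IDs). The sources used here pair no ID with a gene name or product, so IDs are printed as they stand, and the 33 lists of pathways and marker genes fixed in advance, partner markers among them, could not be tested, since 0 IDs had a symbol or product. The tests of these lists and their alternatives were therefore not run.

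Log ratios were computed in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). The median signals were background-corrected with normexp and an offset of 50. Mean signals, which the design had named, were not used here, and the median signals took their place. Log2 ratios of Cy5 over Cy3 were normalised by loess within each array, with control and outlier spots at weight 0, and no step between arrays was applied. Control spots and spots that the scanner software marked as non-uniform or population outliers in either channel were left out (3.54% to 5.69% of spots per array). A spot was tested if its Cy5 signal was well above background on all arrays of at least 1 group, which left 4150 spots of 1780 IDs. The tested spots of an ID were averaged, and the 1689 IDs with at least 2 values in each group were fitted with lmFit and eBayes, co-culture minus mono-culture, two-sided, with the Benjamini-Hochberg adjustment over all 1689 IDs and a threshold of 0.05. All adjusted p-values of single IDs come from limma. Folds are 2 to the power of the log2 difference, after the offset. An ID whose spots were never well above background in a group has only a bound there, and no fold is given for those.

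The groups, the test, the alternatives and the rule for the IDs named were fixed before the data were examined. The rule took, among IDs past the threshold whose 3 co-culture values all lie on one side of the 3 mono-culture values, the 2 with the largest rise and the 2 with the largest fall. Its other parts needed product names. The shares of the ID series, the relation between consecutive ID numbers and the runs were added after the data were seen. Shares were tested with a two-sided Fisher's exact test of each series against the others, and again by rotating the calls along the ordered IDs (all 1689 rotations), which keeps neighbours together; both were adjusted over the 3 series. The relation of consecutive IDs was tested with a two-sided permutation test with 1e+05 permutations, adjusted over 6 distances, and the number of runs with 10000 permutations of the calls. These relations run across IDs, which are not independent replicates.

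The fitting steps were tested on simulated data for the comparison of co-culture with mono-culture, with 1689 IDs on spots as dim as the real ones. Of 100 IDs changed by 2-fold, 89 were recovered with a median estimated log2 difference of 0.47, and of 100 changed by 4-fold, 100 were recovered with a median of 0.89. Of 191 calls, 2 (1.05%) were of unchanged IDs. The simulated Cy5 noise was drawn separately for each array, without an effect of scan or slide position on the ratio. Each simulated change was split evenly between the groups. All simulated IDs had the same noise SD between arrays, while the real IDs differed in theirs. That SD came from log ratios already pressed by the offset, which then pressed it again. The share of false calls therefore does not carry over to the real arrays, where scan and group coincide. Nor do the shares recovered. The offset presses the ratios of dim spots towards 0, so log2 differences given here understate the change.

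Precision is limited by the number of arrays and by dim signals. Median Cy5 signal over local background was 22, 12 and 9 in co-culture replicates 1, 2 and 3, and 31.5, 11 and 9 in the mono-culture ones, over backgrounds of 45 or 46, and 0 spots were saturated. The software's ratio of Cy3 to Cy5 dye factors was 1.20, 1.31 and 1.25 in co-culture and 0.938, 1.00 and 0.947 in mono-culture.

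Per the file headers, the 3 co-culture arrays belong to 1 scan and the 3 mono-culture arrays to another, so scan and group cannot be told apart and the slide could not be taken as a block. The replicate number is also the position of the array on its slide in both groups. Whether the numbers pair the samples was checked by correlating the arrays' deviations from their group means across IDs. The r was 0.240 to 0.275 for the same number and -0.185 to -0.0531 for different numbers. Deviations within a group sum to 0 for each ID, so positive values for the same number bring negative ones for different numbers. By the rule set for this check, every same-number pair being over 0.1, the numbers pair the arrays. No label says what a shared number stands for, and slide position cannot be told apart from anything else that arrays of one number share. The main fit did not use the replicate number, and a fit with it as a block was run as an alternative.

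Alternatives covered background correction, normalisation within arrays, the Cy5 channel alone, the deposited value table, the filter on dim spots, spots with outlier marks, the spot that stands for an ID, the variance model, the replicate block, and leaving out each array in turn. Aquantile scaling between arrays was also run, but it leaves log ratios as they are, so it tests nothing here and is not counted among the alternatives. After the data were seen, an offset of 10, centring in bands of 24 rows, the middle rows 49 to 144, leaving out both arrays numbered 2, IDs with at least 2 tested spots, and the brightest IDs alone (the top 1 of 4 equal groups by mean intensity) were added.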

Results

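Ketogulonicigenium vulgare is a bacterium that oxidises L-sorbose to 2-keto-L-gulonic acid, the precursor of vitamin C. It grows poorly by itself and is usually fermented together with a Bacillus species as companion. Strain WSH-001 was grown here either with Bacillus megaterium or alone, in defined medium at 30 °C, pH 7 and 200 rpm, and RNA was taken after 18 h, in mid-log phase. The question was how the transcript levels of K. vulgare differ between the mixed culture and the pure culture. There were 3 co-cultures and 3 mono-cultures, each on 1 array, with 1 µg of total RNA amplified and labelled with Cy5 and the pool of all 6 cultures labelled with Cy3 as the reference.

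The array carries 3060 IDs in 3 series, 2601 whose IDs begin with KVU alone, 244 with KVU_PA and 215 with KVU_PB. The K. vulgare genome consists of a chromosome and a pair of plasmids; which series belongs to which of them is not given in the sources used here. The spots were dim: in the Cy5 channel 44.1%, 34.3% and 32.4% of the spots of IDs were well above background in co-culture replicates 1, 2 and 3, and 52.3%, 40.5% and 40.4% in the mono-culture ones. In the Cy3 channel, which holds the same pool on each array, the shares were 54.8%, 35.5% and 35.9% on the co-culture arrays and 59.3%, 43.8% and 43.4% on the mono-culture arrays. The signal also changed along the array, with a different profile on the arrays numbered 2. On co-culture replicate 1, 63.5% of Cy5 spots in rows 49 to 72 but 1.44% in rows 169 to 192 were well above background, while on co-culture replicate 2 the share was 2.37% in rows 1 to 24 and 53.3% in rows 97 to 120. On mono-culture replicate 2, the same bands had 4.64% and 57.6%. The pattern of brightness over the spots of an ID correlated with r of 0.959 to 0.972 between arrays at the same position on their slides, with 0.669 to 0.734 between arrays numbered 1 and 3, and with 0.084 to 0.191 between the arrays numbered 2 and the others.

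**Figure D1:**
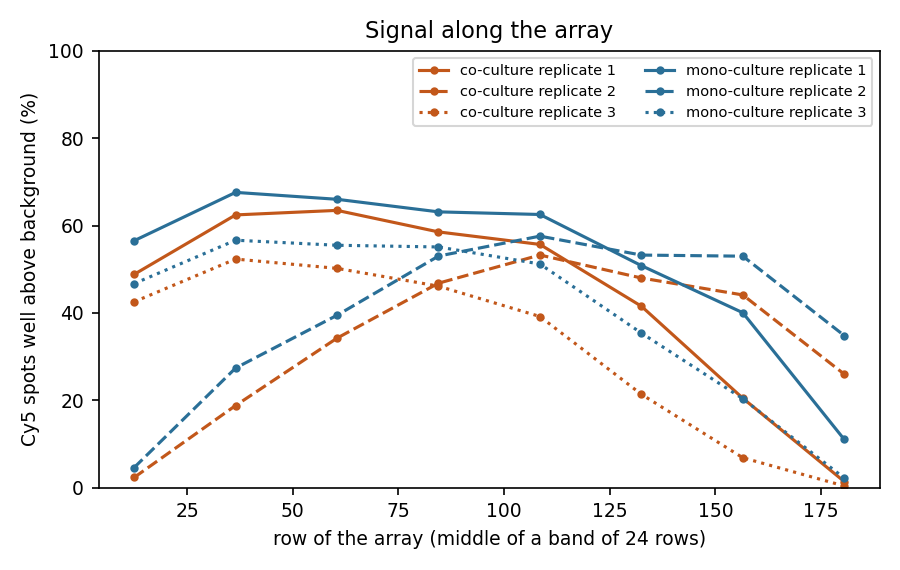
Percentage of Cy5 spots well above background in bands of 24 rows (y axis) against the row of the array (x axis), 1 line per array, co-culture in orange and mono-culture in blue. Both arrays numbered 2 (dashed) are dim in the first rows, at 2.37% and 4.64%, and the arrays numbered 1 and 3 are dim in the last rows.

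Of 1689 tested IDs, 204 were higher and 310 were lower in co-culture than in mono-culture past the limma adjusted p threshold of 0.05, together 30.4% of those tested. From the dimmest to the brightest of 4 equal groups of IDs by mean intensity, the share called was 16.1%, 23.7%, 34.6% and 47.3% (Clopper-Pearson 95% interval of the last 42.4% to 52.2%). The IDs that rose had a median log2 difference of 0.46 (0.18 to 1.97), and those that fell had a median of -0.40 (-0.17 to -1.99). Log ratios of arrays of the same group correlated across IDs with r of 0.687 to 0.822 in co-culture and 0.808 to 0.920 in mono-culture, against 0.295 to 0.397 between the groups. The median over all tested IDs was -0.05, and the median standard error of a difference was 0.0755. Among the 1488 IDs with a value on all 6 arrays, the 3 co-culture values lay entirely above or below the 3 mono-culture values in 777 (52.2%), where chance gives 10%. This held for 474 of the 475 called IDs with 6 values, which the call itself makes likely and which adds no support. The 10% takes the arrays as exchangeable. Arrays of a group share a scan and same-number arrays deviate together, so the excess over 10% does not tell culture from scan. The split into higher and lower depended on the centring: median centring in place of loess gave 329 higher and 187 lower (63.8% of the calls higher, against 39.7% with loess), centring in bands of 24 rows gave 240 and 242 (49.8% higher). The Cy5 signal alone, without the reference, gave 15 higher and 11 lower; without co-culture replicate 2 the counts were 124 higher and 174 lower, without co-culture replicate 3 they were 131 and 176, without mono-culture replicate 1 there were 196 lower, and with the brightest spot alone for each ID there were 189 lower.

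**Figure D2:**
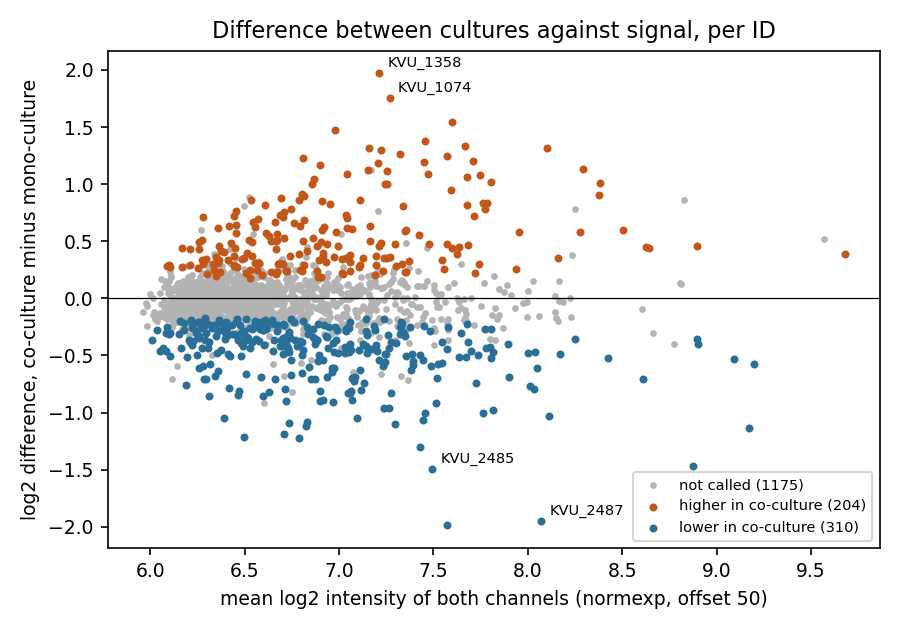
Log2 difference, co-culture minus mono-culture (y axis), of each of the 1689 tested IDs against its mean log2 intensity over both channels (x axis), with the 204 higher IDs in orange, the 310 lower IDs in blue and the others in grey. The 4 named IDs are marked, from 1.97 for KVU_1358 to -1.95 for KVU_2487.

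After the offset, a difference of at least 2-fold was found in 46 of the called IDs, 27 of them higher and 19 lower in co-culture. This count moved with the settings: it was 299 with the scanner software's processed signals, 146 with an offset of 10, 15 with no filter on dim spots and 13 with the Cy5 signal alone. It was 30 without co-culture replicate 1, 30 without co-culture replicate 3 and 27 without mono-culture replicate 1. The offset presses log2 differences towards 0. In the simulated data the median estimate was 0.47 for IDs changed by 2-fold and 0.89 for 4-fold, so IDs changed that much can miss the count.

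Both IDs named for their rise were near the reference in co-culture and far below it in mono-culture. The log2 ratio of KVU_1358 to the reference was 0.21 ± 0.0787 in co-culture and -1.76 ± 0.24 in mono-culture (SD, n = 3 each), a difference of 1.97 (SE 0.12, limma adjusted p = 0.00026), or 3.92-fold. The other, KVU_1074, had 0.26 ± 0.14 in co-culture and -1.49 ± 1.13 in mono-culture (SD, n = 3 each), a difference of 1.75 (SE 0.50, limma adjusted p = 0.0366), or 3.37-fold. Its mono-culture values were spread, -2.17 and -2.11 in replicates 1 and 3 but -0.19 in replicate 2, and rested on 2 spots. With the scanner software's processed signals the rises were 11.3-fold and 15.2-fold. Over the alternatives that tested them, 21 for KVU_1358 and 19 for KVU_1074 of 23, the limma adjusted p ran from 2.39e-06 to 0.58 and from 5.54e-05 to 0.469, the highest in each case with the Cy5 signal alone, which ended both calls at log2 differences of 0.79 and 1.33. For KVU_1358 the 0.79 in Cy5 was well below the 1.97 of the ratio. The rest lay in the Cy3 reference or in the different normalisation of the Cy5 signal, which were not told apart here. KVU_1074 also lost its call with no filter on dim spots (adjusted p = 0.0863) and on leaving out any single array (adjusted p = 0.0832 to 0.117) except mono-culture replicate 2. Its log2 difference was 1.41 to 1.78 in those fits without an array. Without mono-culture replicate 2 it was 2.39 (limma adjusted p = 0.000281). Neither ID was tested with the brightest spot or in the deposited table, nor was KVU_1074 with the filter on both channels or in the middle rows.

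Both IDs named for their fall lay above the reference in mono-culture and slightly below it in co-culture. For KVU_2487 the log2 ratio was -0.31 ± 0.0476 in co-culture and 1.64 ± 0.0210 in mono-culture (SD, n = 3 each), a difference of -1.95 (SE 0.0529, limma adjusted p = 5.03e-06), or 3.86-fold lower. For KVU_2485 it was -0.21 ± 0.18 in co-culture and 1.29 ± 0.39 in mono-culture (SD, n = 3 each), a difference of -1.50 (SE 0.19, limma adjusted p = 0.00261), or 2.83-fold lower. With the processed signals the falls were 5.26-fold and 4.55-fold. Over the alternatives the limma adjusted p ran from 1.34e-05 to 0.166 for KVU_2485, whose call was lost with the Cy5 signal alone at a log2 difference of -1.40, and from 2.23e-06 to 0.0223 for KVU_2487.

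**Figure D3:**
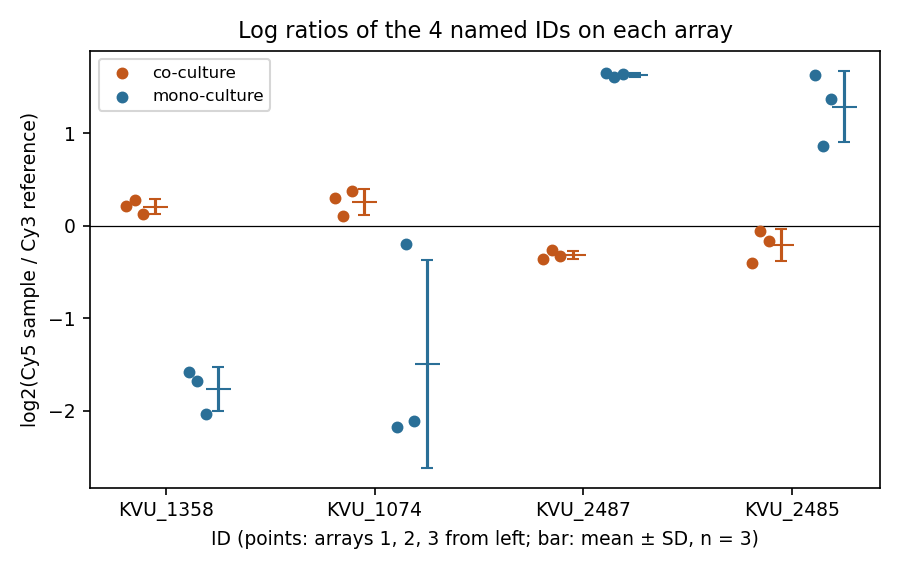
Log2 ratio of the Cy5 sample to the Cy3 reference (y axis) of the 4 named IDs on each array, co-culture in orange and mono-culture in blue, with the mean and SD of the 3 arrays of a group as bars. Co-culture values stay between -0.40 and 0.37, while mono-culture values reach -2.17 for KVU_1074 and 1.65 for KVU_2487.

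By ID series, 448 of 1527 tested KVU IDs changed (29.3%; 171 higher, 277 lower), 33 of 78 KVU_PA IDs (42.3%; 17 higher, 16 lower) and 33 of 84 KVU_PB IDs (39.3%; 16 higher, 17 lower). Median log2 differences were -0.05, 0.07 and -0.01. Taken as independent IDs, the shares of the KVU and KVU_PA series differed from the rest (Fisher's exact test, two-sided, adjusted p = 0.0118 and 0.0348) and that of KVU_PB did not pass (0.0878). Under rotation of the calls along the ordered IDs, none of the 3 shares passed (adjusted p = 0.246, 0.246 and 0.355), nor did the medians (0.0568, 0.0568 and 0.340). KVU_PA had the highest share in 21 of 23 alternatives and KVU the lowest in 20. These alternatives reprocess the same arrays, so the repeated order is not independent support. The exceptions for KVU were no filter on dim spots (15.8%, 13.1% and 12.6%), Cy5 alone (1.31%, 7.69% and 0%) and spots well above background in both channels on all 6 arrays (33.8%, 52.2% and 31%). Fewer of the KVU_PA and KVU_PB IDs could be tested, 32.0% and 39.1% against 58.7% of the KVU IDs. On leaving out single arrays, the shares changed were lowest without co-culture replicate 2, at 15.9% for KVU, 22.9% for KVU_PA and 16.7% for KVU_PB. They were highest without mono-culture replicate 2, at 29.4%, 37.2% and 33.3%.

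IDs with consecutive numbers changed together. Over 1116 pairs of tested IDs that follow each other in number, the log2 differences correlated with r = 0.532 and rho = 0.451 (permutation p = 1e-05, the smallest the permutations can give; adjusted p = 2e-05). The correlation was 0.346 at a distance of 2 numbers, 0.236 at 3, 0.149 at 5 (adjusted p = 4.5e-05), 0.0865 at 10 (adjusted p = 0.00784) and 0.00998 at 20 (adjusted p = 0.758). In 168 pairs both IDs were called, and in 151 of these (89.9%) both went the same way. The called IDs formed 30 runs of 3 or more consecutive numbers in 1 direction, holding 111 IDs or 21.6% of all calls, where shuffled calls gave a mean of 5.37 runs and at most 17 (permutation p = 1e-04, the smallest possible). Of these runs 8 were higher in co-culture, with 30 IDs, and 22 were lower, with 81 IDs. The longest held 7 IDs. These directions rest on the loess calls, whose split into higher and lower depended on the centring. No split of the runs is given here for other centring. All 4 named IDs lay in such runs. The run with KVU_1358 had 4 IDs with a median log2 difference of 1.35 (0.86 to 1.97), the run with KVU_1074 had 4 IDs with a median of 1.37 (1.00 to 1.75), and KVU_2485 and KVU_2487 shared a run of 3 IDs with a median of -1.50 (-1.95 to -0.85).

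**Figure D4:**
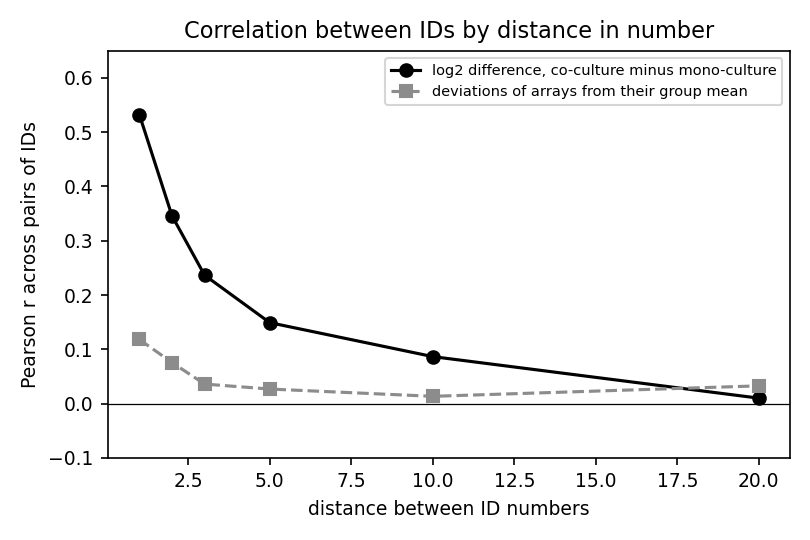
Pearson correlation across pairs of IDs (y axis) against the distance between their numbers (x axis), for the log2 difference between cultures (black) and for the deviations of single arrays from their group mean (grey). The correlation of the differences falls from 0.532 at a distance of 1 to 0.00998 at 20, and that of the deviations is 0.118 at 1.

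The authors' deposited value table listed 1234 IDs, and each of these was lower in co-culture than in mono-culture, with differences of group means from -0.000483 to -2.81 on the log2 scale. Of the 1826 IDs outside the table, 1535 (84.1%) were higher in co-culture by the processed signals of the same arrays. The table held 304 of the 310 IDs called lower here and 0 of the 204 called higher. A limma fit to its values called 366 IDs lower and 0 higher, which follows from the direction of every ID listed and says nothing about rises.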

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

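The tests of a scan effect, on both dyes and on Cy5 alone, and that of dimmer arrays were chosen only after the calls were seen.

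Over all 6 arrays, spots of 3 control classes, which no comparison used, gave signal above that of the negative controls, of whose Cy5 readings 0.433% were well above background. The share was 25.5% for spots named DCP (one-sided Fisher's exact test, p = 2.13e-27), 9.5% for E1A spike-in spots (p = 9.55e-15) and 3.47% for spots named eQC (p = 0.00984). By the same exact test, spots named ETG, at 1.5% (p = 0.092), and RC, at 0.231% (p = 0.862), did not pass, and corner spots were at 0.340%. Readings of the same spot on 6 arrays are not independent, so these p-values are too small. By group, the shares in co-culture and mono-culture were 22.2% and 28.7% for DCP, 5.33% and 13.7% for E1A, 0% and 6.94% for eQC, and 0.866% and 0% for the negative controls, so eQC, with 5 readings well above background in all, was above them in mono-culture only.

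The 514 IDs called different between the cultures were set against technical explanations. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05: the real split gave 514 calls, the highest other split gave 0, and so 1 split gave as many; of the 4 splits that part all 3 same-number pairs, the other 3 gave 0 each. Each other split mixes the cultures, which puts their difference into the spread and holds calls down, so the 0 calls add no support. A slide or scan effect of equal size on both dyes cancels in the ratio, and an unequal one on both should move the Cy3 reference the same way as Cy5, but on same-number arrays left out of the calls the Cy3 share of the Cy5 difference was -0.067 (bootstrap 95% interval over IDs -0.181 to 0.0188), -0.0882 (-0.174 to -0.0144) and -0.253 (-0.442 to -0.122) for numbers 1, 2 and 3, so that in the last 2 pairs part of the ratio difference lay in the reference dye, moving against Cy5. Ratios of the dimmer co-culture arrays pressed towards 0 should, as the whole cause, keep their sign. A co-culture array left out of the calls would then carry a share of 0 or less of the difference. The lowest share for the 3 such arrays was 0.092 (bootstrap 95% interval over IDs 0.0503 to 0.139). That speaks only to pressing as the whole cause, and pressing as a part of it, even a large one, stays open. The bootstrap intervals run over IDs, which are not independent replicates, and hold no spread between arrays. An effect of the scan that differs between the dyes, such as one on Cy5 alone, cannot be told apart from the culture, since 0 scans hold arrays of both groups, and partner RNA binding to K. vulgare probes and the culture difference itself stay open and untested.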

How the results depend on the processing

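The offset of 10, the settings by array position, by number of spots and by brightness of the ID, and the removal of both arrays numbered 2 were chosen only after the data were seen. No alternative compared by ID (all but the deposited table and the settings by spot number and brightness) gave a call in the opposite direction. Of the 514 calls, 513 kept their sign with median centring, 497 with Cy5 alone and all of those tested in the other settings so compared. Main counts were 204 higher, 310 lower and 46 at least 2-fold. With the replicate number as a block they were 203, 320 and 46, sharing 183 of the 204 higher and 280 of the 310 lower calls, and the block ended no call of a named ID. Counts beyond 1.5 times the main ones were, for higher IDs, 329 with median centring, 15 with Cy5 alone (245 IDs at an unadjusted p under 0.05 in limma), 0 with the deposited table and 89 among the brightest IDs. For lower IDs they were 187 with median centring, 11 with Cy5 alone, 189 with the brightest spot and 118 among the brightest IDs. For 2-fold IDs they were 299 with processed signals, 13 with Cy5 alone, 15 with no filter, 94 with the deposited table and 146 with the offset of 10. Leaving out each array in turn gave 124 (co-culture replicate 2) to 223 (mono-culture replicate 2) higher, 174 to 341 lower with the same arrays, and 27 (mono-culture replicate 1) to 50 (mono-culture replicate 2) at least 2-fold; without co-culture replicate 3 the counts were 131, 176 and 30, without mono-culture replicate 1 there were 196 lower, and without co-culture replicate 1 there were 30 at least 2-fold. Fewer IDs (423) enter the brightest group and the deposited table lists only falls. The offset of 10 differs from the main fit in the offset alone, so its 146 IDs follow from less pressing of the ratios. Processed signals have no offset but differ in other steps as well. The cause was not tested for the other settings. Of the named IDs' values 77 kept their call, 9 lost it and 0 reversed, with ranges of 0.79 to 3.50 for KVU_1358, 1.33 to 3.93 for KVU_1074, -2.39 to -1.41 for KVU_2487 and -2.19 to -1.14 for KVU_2485. The correlation of consecutive IDs ran from 0.430 to 0.719 over 23 alternatives, and the shares of the ID series moved in 35 values and did not in 34. The slide as a block and the gene-list alternatives were not run, as each scan holds 1 group and no ID has a name. With the low signal over background, 1689 of the 3060 IDs could be tested.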

Other observations

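The test of transcription in common and that of the mono-culture scan were chosen only after the results were seen.

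Of the tested IDs, 19 were not well above background on any array of 1 group, so no fold is given for them. Of these, 9 were not well above background in mono-culture, 7 of them called higher in co-culture. Another 10 were not well above it in co-culture, 2 of them called lower. All 19 entered the test through the other group alone, so the filter largely set the direction of these calls.

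Consecutive IDs changed together, with r = 0.532. If the layout of the array were the cause, pairs with distant spots should not correlate, but pairs whose nearest spots lay farther apart than the median gave r = 0.474 over 556 pairs. An effect of slide or scan on both dyes, as the whole cause, was predicted to give the Cy3 reference the same correlation, but its r was 0.174. The Cy3 differences were also smaller over all tested IDs (SD 0.217 against 0.398 in Cy5), which can lower r. Such an effect as a part of the correlation therefore stays open. A candidate explanation is that adjacent genes are transcribed together, as in operons, and the fall to r = 0.0865 at a distance of 10 numbers is consistent with that hypothesis. Whether consecutive numbers are adjacent genes on the same strand was not tested here.

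The reference lay closer to the co-cultures than to the mono-cultures in both directions. Called IDs that rose had a median log2 ratio of 0.09 in co-culture and -0.38 in mono-culture, and those that fell had -0.03 and 0.34. A pool with equal amounts of K. vulgare RNA from both cultures would put about 0.5 of the difference on each side. Equal parts of total RNA need not give that, since co-culture RNA can hold RNA of the partner. The share on the co-culture side was at most 0.127 when the difference came from other arrays, a test of array noise shared by the difference and the means. With processed signals, which have no offset, it was at most 0.127. For dim co-culture arrays, it was at most 0.129 in the brightest of 4 equal groups of IDs, whose ratios still carry the offset. None of these brought the share to 0.5, which speaks only to each as the whole cause. As parts of it, array noise, the offset and dim arrays stay open. A Cy5 effect of the mono-culture scan cannot be told apart, as 0 scans hold both groups. Unequal amounts in the pool may be another candidate explanation and were not tested, since the amounts are not given in the sources used here.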
